A study of Mus musculus with 7 samples.

How the data were processed

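The data were RNA sequencing counts of haematopoietic stem cells (HSCs) sorted from mouse bone marrow, the cells from which all blood lineages arise. Per the labels' protocols, marrow was flushed from the femora and tibiae of mice aged 6 to 8 weeks, red cells were lysed and 1500 sorted cells were used per library. Polyadenylated RNA was reverse transcribed by a low-input protocol derived from single-cell RNA sequencing, and the cDNA was amplified with 12 PCR cycles. The surface markers and gates of the sort are not given in the sources used here. The labels put 3 libraries in a control group and 4 in a group named MC38, after a mouse colon carcinoma line that grows in C57BL/6J mice. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

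The authors deposited a single table of read counts per Ensembl gene, with 28786 genes and a column per library. Per the submitters' processing notes, Trim Galore 0.5.0, STAR 2.6.1, HTSeq 0.10.0 and the mm10 build were used. The annotation release, the strand setting and any filter are not given in the sources used here. Without a stated strand, reads of overlapping and antisense genes cannot be assigned with certainty, and reads of near-identical copies, such as immunoglobulin segments, may be lost or split. The protocol names no molecular identifiers, so PCR copies were counted as reads. Symbols and coordinates were taken from GENCODE release 21 for mouse (GRCm38, the assembly of mm10), which named 27728 of the gene IDs. A count was present in at least 1 library for 21675 genes.

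Of the 7 deposited columns, 6 behave as raw counts. Control column 3 is different, although the deposited values are whole numbers too. Among 18542 genes with a count in control replicates 1 or 2, 99.4% had 3 times the column 3 value at or above the sum of the other controls, within a tolerance of 1.5 counts for rounding. All but 1 of the 120 exceptions had equal counts in control replicates 1 and 2, and the remaining exception was Meis1. The ratio of column 3 to that sum had a median of 0.353 over 9652 genes with a sum of at least 200 and unequal counts, with 95% of genes between 0.342 and 0.371. The spread around this line was 0.388 of that of a random subsample of the merged reads. The smallest spread in any triple of columns made without column 3 was 4.41, and an independent library simulated from the data gave 5.07. Column 3 was therefore not used as an independent count library, a decision made after the values were seen. The design fixed before the data were examined had all 7 columns, and that fit is given as an alternative.

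The comparison of MC38 with control was made in edgeR 4.0.16 under R 4.3.3 on 2 control and 4 MC38 libraries. It used TMM normalisation, the filterByExpr filter, the robust quasi-likelihood test and Benjamini-Hochberg adjustment, with a threshold of 0.05 and no block. The filter kept 14226 genes, and the common biological coefficient of variation was 0.366. Values are given as CPM, the counts scaled to a common library total after TMM,, as mean ± SD with n = 2 for control and n = 4 for MC38. All adjusted p-values of single genes are from edgeR unless another tool is named, and all tests were two-sided. A lower bound on a fold change was set against 3 counts over all libraries of the group that had none, and such bounds cover counting error only.

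Gene lists fixed before the data were examined, 29 in number, were tested with camera on the edgeR fit, with a preset correlation of 0.01 between genes and adjustment over the 28 lists with at least 5 tested members. The sex-linked list had too few and was not tested. Camera compares the members of a list with all other genes. It was repeated with a correlation estimated per list, and fry from limma 3.58.1 was run as a test of whether members moved one way on balance. The estimates ran from -0.033 for the T and NK cell list to 0.899 for the mitochondrially encoded transcripts. A call lost at an estimate below the preset does not come from members that vary together. The T and NK cell, G1/S (-0.027), NF-kB and TNF (-0.025) and macrophage and dendritic cell (-0.02) lists were such cases. So were the myeloid regulator (-0.016), ER stress (-0.015), B cell (-0.01) and megakaryocyte and erythroid (-0.002) lists.

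The genes named were chosen by a rule fixed before the data were examined. It took the 10 genes with the largest change in each direction among those past the threshold, with a mean of at least 5 CPM over the 7 columns and no overlap between groups, leaving out predicted and clone-named genes. It also took 11 genes tied to the question and the 4 members of smallest p in each list. The result of 1 of these genes is not reported here. Since immunoglobulin segments filled 19 of the 20 places, the first part was repeated without them after the values were seen.

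Simulated counts with known changes were used to check the test. With 2 control and 4 MC38 libraries and 13786 genes, 36.8% of genes changed 2-fold and 59.6% of genes changed 4-fold were recovered, none with the wrong sign. Genes simulated without change made up 7.07% of the calls, and camera found a shifted list while 0 of 20 random lists passed. The simulated genes varied independently of each other, so this does not check camera for lists whose members vary together. Alternatives covered normalisation, filters, thresholds, each library left out, a replicate block, DESeq2 1.42.0, limma-voom, other set tests, the 7-column fit, a control library rebuilt from column 3 and the removal of immunoglobulin genes. The rebuilt control and the removal of immunoglobulin genes were added after the data were seen. The 7-column fit was fixed before and became an alternative then. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for tables and the exact permutation test.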

Results

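Transcript levels were measured in cells sorted as HSCs from the bone marrow of control mice and of mice bearing MC38 tumours. Bulk libraries do not place a transcript in a cell. A change below, also of granule, immunoglobulin or mature cell genes, may therefore lie in HSCs or in other cells of the sorted samples. The series asks how a tumour biases HSCs towards the myeloid lineage, and its title places interferon gamma and the transcription factor Meis1 in that process. The 2 control libraries used for testing held 12131546 and 12306066 counts, and the 4 MC38 libraries held between 13368238 and 17657037. Control column 3 held 8625380, but its values follow those of the other controls too closely to be independent counts, and it does not enter the values below unless named. The 10 most abundant genes took 9.11 ± 0.52% of counts in control and 10.04 ± 0.15% in MC38 libraries (SD, n = 2 and 4).

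**Figure D1:**
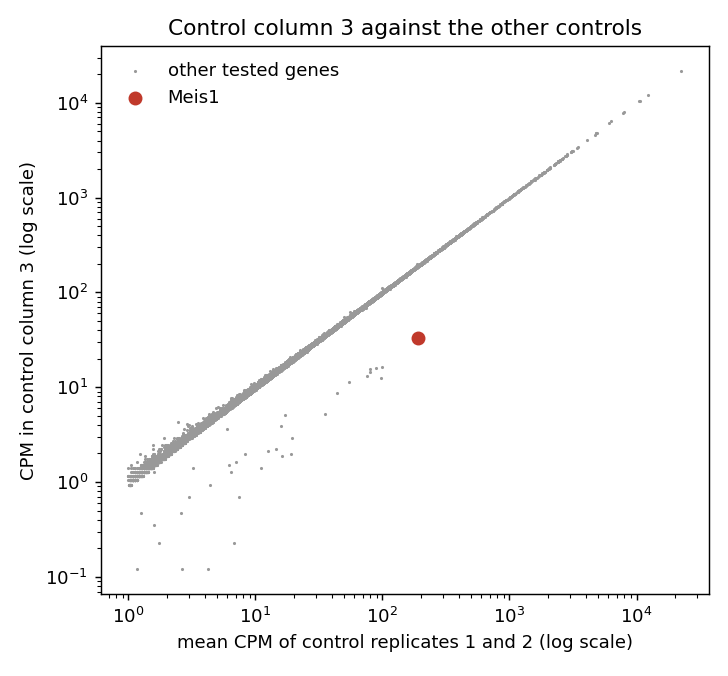
Each point is a tested gene, with the mean CPM of control replicates 1 and 2 on the horizontal log axis and CPM in control column 3 on the vertical log axis. Most genes lie on a narrow line, while Meis1 (red) has 33.1 CPM in column 3 against a mean of 192 CPM in the other controls.

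The myeloid granule and maturation list moved up in MC38 (median log2 fold change 0.76), and many immunoglobulin segments differed between the groups. Lists of immediate early, heat shock and G2/M genes moved down. Lists of lymphoid priming genes and of mature T and NK cell markers moved up, though no member of the T and NK cell list was called. The granule, immediate early, heat shock, G2/M, lymphoid priming and T and NK cell lists passed with camera, and all but the heat shock and T and NK cell lists (adjusted p = 0.0796 for both) also with an estimated correlation. The main regulators of stem cell identity did not pass the test, Meis1 among them. Of 14226 genes tested, 148 were higher and 81 lower in MC38 (edgeR, adjusted p under 0.05). At least a 2-fold change was found for 106 and 41 of these, and immunoglobulin genes made up 28 and 17 of them. All of these genes were higher, or lower, in every MC38 library than in every control column. This separation was present in 28.7% of all tested genes, against 5.71% by chance for 3 against 4 libraries and 13.3% for 2 against 4.

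The counts depended on single libraries. Without control replicate 1, 44 genes were higher and 16 lower, and without control replicate 2, 58 and 25. Leaving out MC38 replicate 1 gave 259 and 183, replicate 2 gave 69 and 28, and replicate 4 gave 77 and 31. The 7-column fit called 791 higher and 663 lower, and these included 146 of the 148 and all 81. Of the 28 gene lists tested, 18 passed with camera, 10 up and 8 down. Of the 74 named genes past the threshold, 29 passed without control replicate 1, 34 without control replicate 2, 42 without MC38 replicate 2, 44 without MC38 replicate 4 and 22 in every alternative that tests them. Over the alternatives the lowest adjusted p of each of the 74 was 0.00141 or lower, but such a minimum picks the most favourable fit and adds no support. A value given for a lost call is the highest over the alternatives of that gene unless others stand beside it. A gene given with 1 such value may have lost its call in other alternatives too. Ccr7, Ccr9, Gab3 and Klra17, for example, also lost theirs with limma-voom, with and without quality weights. With an estimated correlation 4 lists passed, the granule, lymphoid priming, immediate early and G2/M lists.

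**Figure D2:**
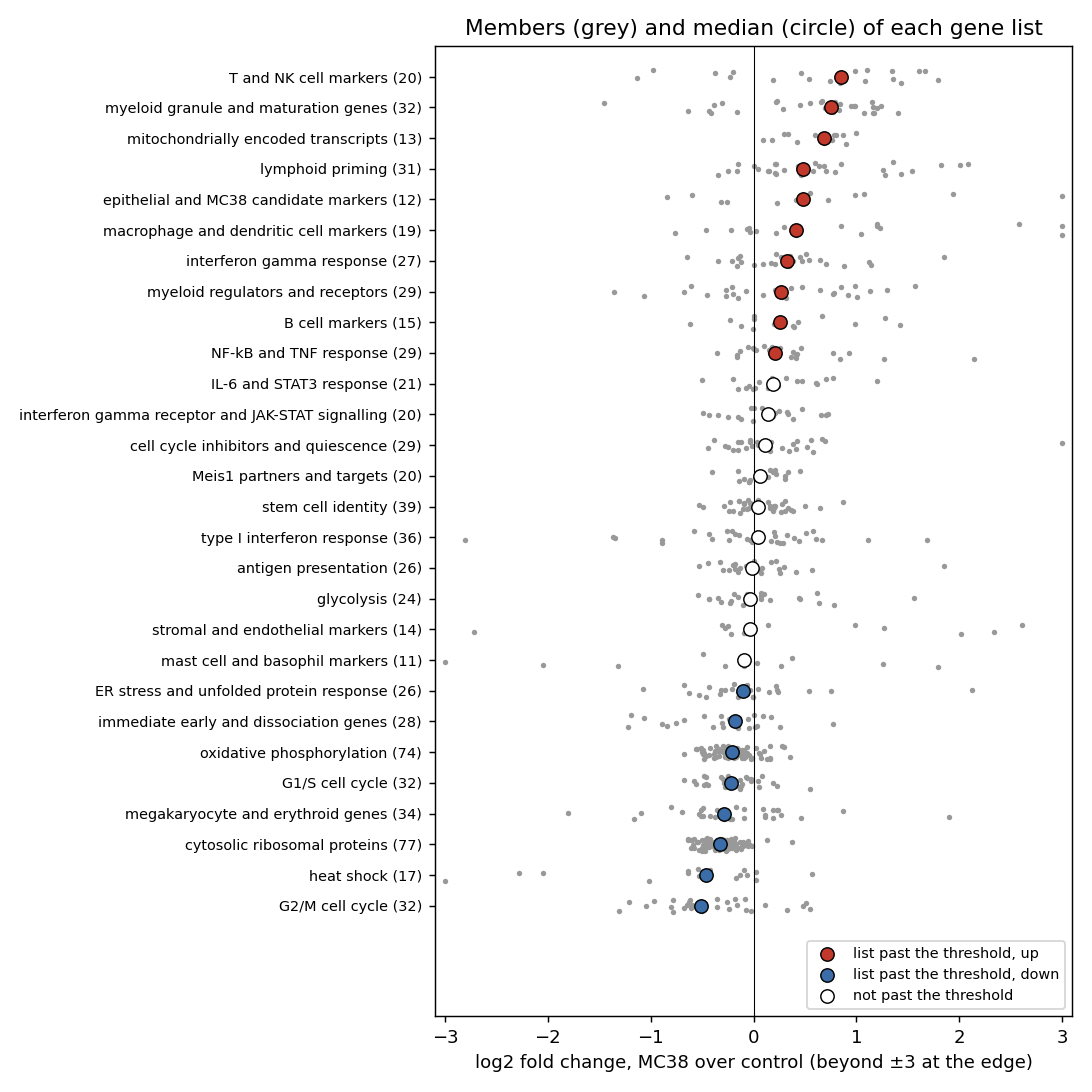
The log2 fold change of MC38 over control is shown for each tested member (grey) and for the median (circle) of each list, with the number of tested members in brackets and colour for lists past the camera threshold. Medians run from -0.52 for the G2/M list to 0.85 for the T and NK cell list, and members beyond 3 on either side are drawn at the edge.

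Myeloid granule and maturation transcripts rose as a group in MC38. S100a8 and S100a9, which encode the calprotectin subunits of neutrophils, went from 10390 ± 375 to 20060 ± 797 CPM (1.93-fold) and from 8011 ± 43.6 to 17870 ± 1708 CPM (2.23-fold; SD, n = 2 and 4). Ngp (ENSMUSG00000032484, chromosome 9: 110419747 to 110423012), a secondary granule protein, rose from 4091 ± 174 to 9125 ± 132 CPM (log2 fold change 1.16, SE 0.10, edgeR adjusted p = 0.000345). Retnlg, a resistin-like secreted protein, rose 2.30-fold (edgeR adjusted p = 0.000532), and Mmp8, the neutrophil collagenase, rose 2.65-fold from 165 ± 8.13 CPM (edgeR adjusted p = 0.000796). Mpo, the myeloperoxidase of early granules, moved the other way and fell from 1595 ± 63.2 to 1022 ± 105 CPM (edgeR adjusted p = 0.0304). The other early granule protease genes did not pass: Elane was at 2086 ± 157 and 1681 ± 215 CPM (edgeR adjusted p = 0.263) and Prtn3 at 1185 ± 120 and 875 ± 135 CPM (edgeR adjusted p = 0.173). Of the 32 members tested, 12 rose, 1 fell and 19 did not pass. Adjusted over the list alone, 20 rose and 5 fell. S100a8, Elane and Prtn3 lie outside the naming rule and were chosen after their values were seen. The list moved up with a median log2 fold change of 0.76 (camera adjusted p = 7.64e-16, and adjusted p = 0.0326 with an estimated correlation). S100a8, S100a9, Ngp, Camp, Ltf and Lcn2 together took 2.59 ± 0.008% of counts in control and 5.43 ± 0.25% in MC38 libraries. S100a9, Ngp, Retnlg and Mmp8 passed in every alternative, while Mpo did not without control replicate 1 (edgeR adjusted p = 0.239), control replicate 2 (0.123), MC38 replicate 2 (0.103) or MC38 replicate 4 (0.12).

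**Figure D3:**
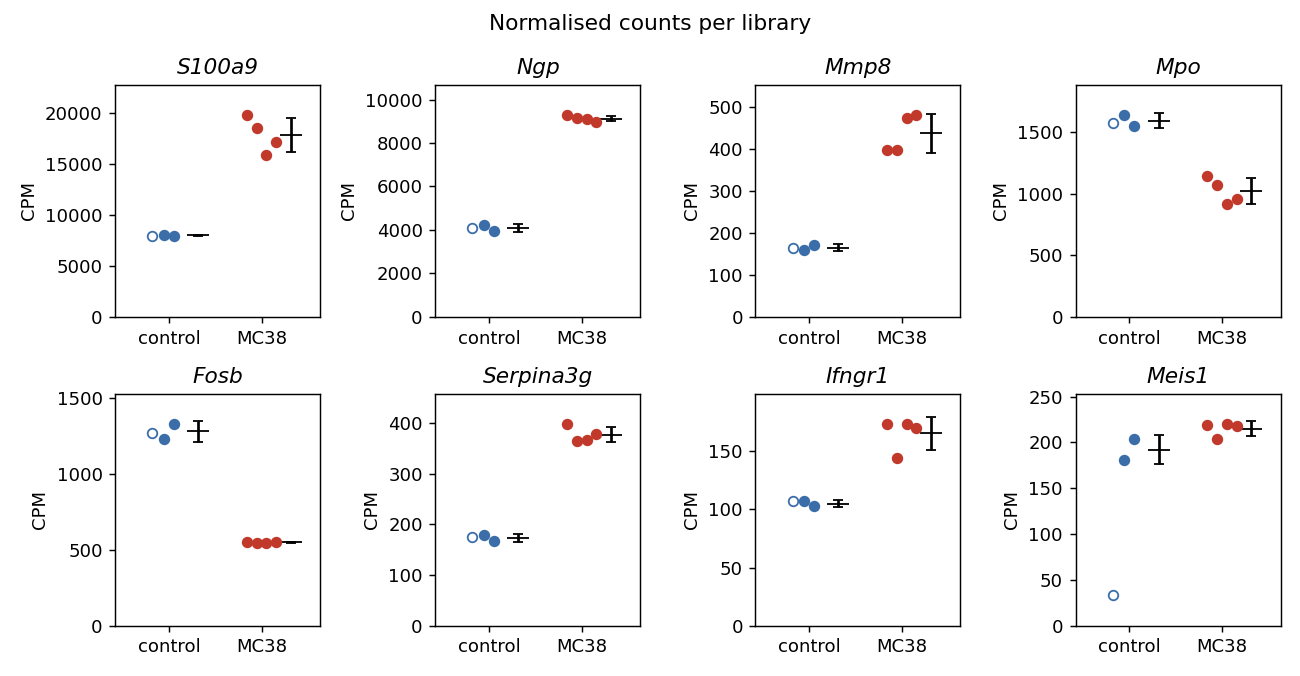
CPM per library is shown for 8 genes, with control in blue, MC38 in red, control column 3 as an open circle and mean ± SD of the filled points beside them. S100a9, Ngp and Mmp8 are higher in every MC38 library, Mpo and Fosb are lower, and Meis1 is at 282 counts in column 3 against 2151 and 2464 in the other controls.

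Several myeloid regulators and receptors rose, as did the granule list above and, below, the lists of T and NK cell and of macrophage and dendritic cell markers. The lists of T and NK cell and of macrophage and dendritic cell markers did not pass with an estimated correlation (camera adjusted p = 0.0796 for both). Fcer1g and Tyrobp, signalling adaptors also expressed in mature myeloid and NK cells, rose 1.89-fold and 1.71-fold (edgeR adjusted p = 0.00444 and 0.0161). Id2, an inhibitor of E-proteins, rose 2.01-fold (edgeR adjusted p = 0.0215). Klf4, a factor of monocyte differentiation that is also an immediate early gene, fell from 409 ± 11.4 to 195 ± 28.8 CPM (edgeR adjusted p = 0.00545). The lineage factors Spi1 (222 ± 28.9 and 269 ± 22.6 CPM, edgeR adjusted p = 0.31) and Cebpa (18.8 ± 0.88 and 15.6 ± 5.85 CPM, edgeR adjusted p = 0.748) did not pass. Of 29 members tested, 5 rose, 1 fell and 23 did not pass, and 10 rose and 2 fell adjusted over the list alone. The list passed with camera (adjusted p = 0.00563), but not with an estimated correlation (adjusted p = 0.0796). Leaving out control replicate 1 ended the calls of Fcer1g (0.0797), Tyrobp (0.179), Id2 (0.23) and Klf4 (0.112).

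Many immunoglobulin kappa segments differed between the groups, in both directions. Igkv8-16 (ENSMUSG00000076591, chromosome 6: 70386672 to 70387252) had no count in the controls and 861 to 978 counts in the MC38 libraries, at least 472-fold higher. Igkv4-57-1 and Igkv10-94 were likewise at 0 in the controls and at least 226-fold and 92.9-fold higher. Igkv6-23 went from 0.666 ± 0.11 to 313 ± 26.9 CPM (log2 fold change 8.86, edgeR adjusted p = 8.95e-08). Igkv8-28, Igkv5-43, Igkv4-70, Igkv4-58 and Igkv5-48 also rose, each from a mean below 0.3 CPM. In the other direction, Igkv2-112 had 307 and 201 counts in the controls and none in MC38, at least 430-fold lower. Igkv6-20 fell from 128 ± 4.96 to 0.298 ± 0.31 CPM (edgeR adjusted p = 4.02e-05), and Igkv4-86, Igkv14-111, Igkv3-5, Igkv4-91, Igkv1-110, Igkv6-32 and Ighv1-39 fell as well. Ighg1, the constant region of IgG1, had 0 and 3 counts in the controls and 625 to 909 in MC38 libraries (edgeR adjusted p = 5.83e-05). Of 96 immunoglobulin genes tested, 28 rose and 17 fell, and together these genes took 0.546 ± 0.06% of control and 0.802 ± 0.065% of MC38 counts (SD, n = 2 and 4). Segments share sequence, so the counts of a single segment are uncertain. With limma-voom the adjusted p was 0.069 for Igkv8-28 and Igkv10-94, 0.102 for Ighg1, 0.115 for Igkv4-58 and 0.136 for Igkv5-48, and Igkv3-5 (0.113), Igkv1-110 (0.223), Igkv6-32 (0.113) and Ighv1-39 (0.0795) did not without control replicate 1.

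**Figure D4:**
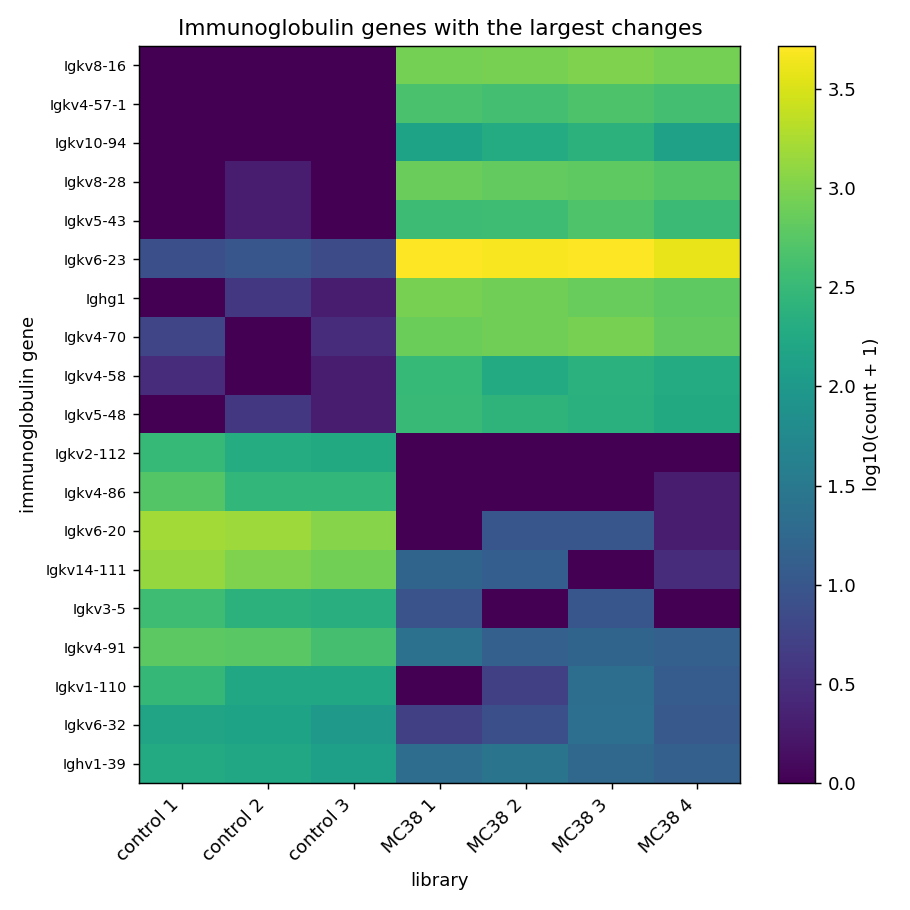
Colour gives log10 of count plus 1 for the 19 immunoglobulin genes with the largest changes (vertical) in each of the 7 columns (horizontal). The upper 10 genes have at most 9 counts in any control column, and the lower 9 have far fewer counts in the MC38 libraries than in the controls.

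Among the other genes with the largest changes, Ifitm6, a member of the interferon-induced transmembrane family, rose from 71.8 ± 9.32 to 317 ± 9.99 CPM (4.41-fold, edgeR adjusted p = 5.24e-05). Stfa1, a stefin A protease inhibitor of a multigene family, rose 5.42-fold (edgeR adjusted p = 0.0106), and Inhba, the activin A subunit, rose 6.2-fold from 1.66 ± 0.92 CPM (edgeR adjusted p = 0.0305). Gab3, Rasd1 and Klra17 rose between 3.77-fold and 4.04-fold. Kifc1, a kinesin motor of the mitotic spindle, fell from 14.3 ± 3.83 to 1.83 ± 0.35 CPM (edgeR adjusted p = 0.00635). Prg2, the eosinophil major basic protein, fell from 23.1 ± 3.48 to 5.57 ± 1.89 CPM (edgeR adjusted p = 0.0256). C2cd4b, Exoc3l4, Ube2cbp and Dand5 fell too, each from below 20 CPM. Ifitm6 passed in every alternative. For the others without control replicate 1 the adjusted p was 0.12 for Stfa1, 0.179 for Inhba, 0.127 for Kifc1 and 0.142 for Prg2 (edgeR), and it ran from 0.128 (Rasd1) to 0.32 (Dand5) for the rest, with Gab3 at 0.164, Klra17 at 0.213, Ube2cbp at 0.236, C2cd4b at 0.241 and Exoc3l4 at 0.303.

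Meis1, a homeobox factor that maintains HSCs, did not pass the test. Its gene (ENSMUSG00000020160, chromosome 11: 18879817 to 19018985, mm10) had 192 ± 16.0 CPM in control and 215 ± 7.72 CPM in MC38 libraries, a log2 fold change of 0.16 (SE 0.11, edgeR adjusted p = 0.502). Over the 15 splits of the 6 libraries the exact permutation p was 0.0667, the smallest these splits allow. Every MC38 library (203.6 to 220.1 CPM) was above both controls (180.7 and 203.4 CPM), by little for the nearest libraries. In the 7-column fit the log2 fold change was 0.63 (edgeR adjusted p = 0.448), and the exact permutation test over 35 splits gave p = 0.0286, again the smallest possible. That shift came from column 3, where the value was 282 and the other controls had 2151 and 2464 counts. Meis1 partners and targets did not pass as a list (camera adjusted p = 0.62), with 0 of 20 members called by edgeR or adjusted over the list alone. For stem cell identity, 0 of 39 members were called over all genes and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.62). Kit was at 352 ± 42.8 and 328 ± 29.4 CPM (edgeR adjusted p = 0.731), Flt3 at 112 ± 10.3 and 130 ± 6.89 CPM (0.416), and Gata2 at 321 ± 33.9 and 228 ± 16.6 CPM (0.0726). Over all 14226 genes 2487 had an unadjusted p under 0.05, and DESeq2 called 626 genes higher in MC38 and 395 genes lower in MC38 without calling Meis1 (adjusted p = 0.481).

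Among the interferon gamma response genes a single member was called. Serpina3g, an interferon-inducible protease inhibitor, rose from 173 ± 8.17 to 377 ± 15.3 CPM (log2 fold change 1.13, SE 0.11, edgeR adjusted p = 0.000946) and passed in every alternative. It was the only one of 27 tested members called over all genes, and 5 rose adjusted over the list alone. The list had a median log2 fold change of 0.32 (camera adjusted p = 0.00363). It did not pass with an estimated correlation (camera adjusted p = 0.0891), although that estimate, 0.011, was close to the preset. Ly6a, which encodes the stem cell antigen Sca-1, was at 107 ± 18.5 and 168 ± 8.16 CPM (edgeR adjusted p = 0.0522). Irf1, an interferon-inducible transcription factor, was at 135 ± 8.75 and 135 ± 4.25 CPM (edgeR adjusted p = 0.994). Ifngr1, the ligand-binding receptor chain (chromosome 10: 19591949 to 19610229), rose from 105 ± 3.02 to 166 ± 14.1 CPM (log2 fold change 0.66, SE 0.13, edgeR adjusted p = 0.0405). The partner chain Ifngr2 was at 18.4 ± 7.78 and 30.3 ± 10.3 CPM (edgeR adjusted p = 0.348). Ifngr1 was the 1 member called of 20 in the receptor and JAK-STAT list, where 2 rose adjusted over the list alone (camera adjusted p = 0.152). Fry called that list up (adjusted p = 0.0168), the 1 of its 18 alternatives that passed. No member of the type I interferon list was called among 36 or adjusted over the list alone (camera adjusted p = 0.797), and its median and mean differed in sign (0.04 and -0.06). The Ifngr1 call was lost with limma-voom (adjusted p = 0.0571), with the rebuilt control (0.0944), without immunoglobulin genes (0.0512), and without control replicate 1 (0.22), control replicate 2 (0.157), MC38 replicate 2 (0.0696) or MC38 replicate 4 (0.142), within a range of 0.000272 to 0.22.

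The lymphoid priming list moved up in MC38. So did lists of mature lymphoid markers, given in the next paragraph, which did not pass with an estimated correlation. Ccr7 and Ccr9, chemokine receptors of lymphoid cells, rose 4.00-fold and 4.23-fold, from 3.83 ± 0.28 and 4.76 ± 2.65 CPM (edgeR adjusted p = 0.0166 and 0.0405). Il2rg, the common cytokine receptor chain, rose from 237 ± 22.1 to 369 ± 24.4 CPM (edgeR adjusted p = 0.0333). Of 31 members 3 rose and 28 did not pass, and 11 rose adjusted over the list alone. The list moved up with a median log2 fold change of 0.48 (camera adjusted p = 2.23e-06, and adjusted p = 0.0326 with an estimated correlation). In edgeR Ccr7 did not pass without control replicate 1 (0.119), nor Ccr9 (0.138) or Il2rg (0.163) without control replicate 2.

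Lists of mature cell markers moved up together with the lymphoid priming list. The T and NK cell list moved up with a median of 0.85 (camera adjusted p = 0.000757, but adjusted p = 0.0796 with an estimated correlation). None of its 20 members passed over all genes in edgeR and 7 rose adjusted over the list alone, and Klrb1c was at 6.47 ± 2.26 and 20.6 ± 4.95 CPM (edgeR adjusted p = 0.0541). In the B cell list, Ighm rose from 840 ± 69.1 to 2248 ± 243 CPM (edgeR adjusted p = 0.000744) and Igkc rose 1.58-fold (edgeR adjusted p = 0.0428). Both are immunoglobulin constant regions, and the other 13 of the 15 members did not pass. Adjusted over the list alone 2 rose and 1 fell. The B cell list passed narrowly (camera adjusted p = 0.0426, adjusted p = 0.152 with an estimated correlation) and failed in 7 of 18 alternatives, among them without immunoglobulin genes (0.27), control replicate 2 (0.188) or MC38 replicate 2 (0.0927). Siglech, a plasmacytoid dendritic cell receptor, rose 2.34-fold from 29.4 ± 6.90 CPM (edgeR adjusted p = 0.013). C1qa, a complement gene of macrophages, rose from 0.166 ± 0.12 to 4.31 ± 1.04 CPM (edgeR adjusted p = 0.0342). They were the 2 called of 19 macrophage and dendritic cell genes, with 5 up adjusted over the list alone (camera adjusted p = 0.00171, adjusted p = 0.0796 with an estimated correlation). Siglech did not pass without control replicate 2 (0.091) nor did Igkc (0.191), and C1qa did not with limma-voom (0.203).

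Among 11 mast cell and basophil genes, Hdc, the histamine-forming enzyme, rose from 76.3 ± 3.49 to 183 ± 13.3 CPM (edgeR adjusted p = 0.00105). Mcpt8, a basophil protease, fell from 31.9 ± 0.13 to 7.70 ± 1.29 CPM (edgeR adjusted p = 0.00444). Adjusted over the list alone 2 rose and 3 fell, and the list did not pass (camera adjusted p = 0.592). Stromal and endothelial genes did not pass as a list (camera adjusted p = 0.471). They had 0 of 14 members called in edgeR or adjusted over the list alone, with a median of -0.03 and a mean of 0.39. Fry called that list up (adjusted p = 0.0426), and its other 17 alternatives did not pass. The epithelial list drawn up for the tumour line moved up (camera adjusted p = 0.000953, but adjusted p = 0.199 with an estimated correlation), with 3 of 12 members called and 6 adjusted over the list alone. Those 3 were Lcn2, a neutrophil granule protein also in the granule list, Ceacam1, an adhesion molecule of myeloid and epithelial cells, and Muc1, a membrane mucin at 5.48 ± 2.76 and 21 ± 1.52 CPM. Without control replicate 1 the edgeR adjusted p was 0.0665 for Mcpt8, 0.0797 for Lcn2, 0.145 for Ceacam1 and 0.161 for Muc1.

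Several immediate early genes, which respond within minutes to stimulation or to tissue dissociation, fell. Fosb, an AP-1 subunit, fell from 1283 ± 69.4 to 550 ± 4.86 CPM (log2 fold change -1.22, SE 0.10, edgeR adjusted p = 0.000256). Klf2, a quiescence factor of lymphocytes and endothelium, fell from 1730 ± 34.7 to 758 ± 79.5 CPM (edgeR adjusted p = 0.000936), and Atf3, a stress factor, from 350 ± 56.8 to 189 ± 13.2 CPM (edgeR adjusted p = 0.009). Of 28 members 6 fell, 1 rose (Fosl2, an AP-1 subunit, named after its value was seen) and 21 did not pass, with 9 down and 1 up adjusted over the list alone (camera adjusted p = 6.05e-07, adjusted p = 0.0326 with an estimated correlation). Some heat shock genes fell with them. Hspa1a, an inducible Hsp70 with a close copy in Hspa1b, fell from 60.1 ± 2.40 to 14.5 ± 1.12 CPM (edgeR adjusted p = 0.000532). Dnajb1, a co-chaperone of Hsp70, and Hspa8, the constitutive Hsp70, were 1.55-fold and 1.56-fold lower (edgeR adjusted p = 0.0147 and 0.0386). Of 17 members 3 fell and 14 did not pass, and 10 fell adjusted over the list alone (camera adjusted p = 5.23e-08, but adjusted p = 0.0796 with an estimated correlation). In the ER stress list, Hspa5, the main chaperone of the endoplasmic reticulum, fell from 1973 ± 0.99 to 936 ± 87.3 CPM (edgeR adjusted p = 0.00117). It was the 1 called of 26, with 6 down adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.0891 with an estimated correlation, 0.0754 without control replicate 1). Fosb, Klf2, Hspa1a and Hspa5 passed in every alternative, while without control replicate 1 Atf3 (0.143), Dnajb1 (0.179) and Hspa8 (0.256) did not.

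Several cell cycle genes of G2 and mitosis fell. Ccnb1 and Ccnb2, the mitotic B cyclins, fell from 40.9 ± 1.98 to 16.5 ± 3.31 CPM and from 81.6 ± 3.44 to 39.5 ± 3.55 CPM (edgeR adjusted p = 0.0268 and 0.0106). Birc5 and Top2a, survivin and topoisomerase II alpha, were 1.72-fold and 1.54-fold lower (edgeR adjusted p = 0.0205 and 0.0347). Of 32 members 4 fell and 28 did not pass, with 10 down adjusted over the list alone (camera adjusted p = 6.44e-07, adjusted p = 0.0326 with an estimated correlation). The G1/S list, replication genes such as Mcm6 (152 ± 10.6 and 103 ± 5.73 CPM, edgeR adjusted p = 0.055), had 0 of 32 called and 1 down adjusted over the list alone (camera adjusted p = 0.00563, adjusted p = 0.0796 with an estimated correlation). Cell cycle inhibitors and quiescence genes had 0 of 29 called, with 4 up and 1 down adjusted over the list alone (camera adjusted p = 0.279). Without control replicate 1 the edgeR adjusted p was 0.2 for Ccnb1, 0.128 for Ccnb2, 0.167 for Birc5 and 0.189 for Top2a.

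The cytosolic ribosomal protein list moved down, with 75 of 77 members below 0 and a median log2 fold change of -0.32. Rpl3, Rplp0, Rpl8 and Rps27a fell and 73 did not pass, and adjusted over the list alone 23 fell and 1 rose (camera adjusted p = 1.59e-13, but adjusted p = 0.152 with an estimated correlation). Rpl3, of the large subunit, went from 2294 ± 117 to 1574 ± 84.8 CPM (edgeR adjusted p = 0.0325). Without control replicate 1 the edgeR adjusted p was 0.256 for Rpl3, 0.27 for Rplp0, 0.276 for Rpl8 and 0.293 for Ndufb5, and without control replicate 2 it was 0.168 for Rps27a. Nuclear-encoded oxidative phosphorylation genes moved down with a median of -0.21, with 1 of 74 called (Ndufb5, a complex I subunit) and 3 adjusted over the list alone. That list passed with camera (adjusted p = 5.37e-06), but not with an estimated correlation (camera adjusted p = 0.296) or fry (adjusted p = 0.0741). The mitochondrially encoded transcripts moved up with a median of 0.68, and all 13 were above 0. None of them was called over all genes in edgeR, while 10 rose adjusted over the list alone. As a list they passed with camera (adjusted p = 1.12e-06), but not with an estimated correlation (camera adjusted p = 0.274) or fry (adjusted p = 0.109). Their share of counts was 1.73 ± 0.028% in control and 2.59 ± 0.52% in MC38 libraries, and that of ribosomal protein genes 10.1 ± 0.44% and 8.21 ± 0.67% (SD, n = 2 and 4). Megakaryocyte and erythroid genes moved down (camera adjusted p = 0.0149, but adjusted p = 0.0891 with an estimated correlation and 0.139 without control replicate 1). Lmna, a nuclear lamin, was the 1 called of 34 over all genes and adjusted over the list alone, and fell 2.23-fold (edgeR adjusted p = 0.0403, and 0.211 without control replicate 1).

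A few genes of inflammatory signalling rose. Il1b, the cytokine interleukin 1 beta, rose from 99.4 ± 10.02 to 240 ± 33.3 CPM and its antagonist Il1rn from 6.15 ± 2.63 to 27.2 ± 3.96 CPM (edgeR adjusted p = 0.00402 and 0.0137). They were the 2 called of 29 in the NF-kB and TNF list, with 5 up adjusted over the list alone (camera adjusted p = 0.00179, but adjusted p = 0.0796 with an estimated correlation). The IL-6 and STAT3 list had 0 of 21 called and 1 up adjusted over the list alone, and did not pass (camera adjusted p = 0.0582). It passed in 5 of 18 alternatives, fry among them (adjusted p = 0.00643). In the glycolysis list Slc16a3, a lactate transporter, rose 2.94-fold from 17.6 ± 1.81 CPM (edgeR adjusted p = 0.00313) as the 1 member called of 24 and adjusted over the list alone (camera adjusted p = 0.954, median -0.03 and mean 0.08). Antigen presentation genes had 0 of 26 called in edgeR or adjusted over the list alone (camera adjusted p = 0.984, median -0.02 and mean 0.05), and B2m, the light chain of MHC class I, was at 2478 ± 192 and 3675 ± 602 CPM (edgeR adjusted p = 0.102). Il1rn (0.113) did not pass without control replicate 1, nor Il1b (0.0759) and Slc16a3 (0.0517) without control replicate 2.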

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

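All tests of explanations in this part, and the comparisons of column 3 with the other controls, were chosen after the results were seen.

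Meis1 had a value of 282 in control column 3, where the controls used had 2151 and 2464 counts, and it is the only gene with unequal counts in those controls that lies below their sum divided by 3. That line would put Meis1 at 1538 or more even with no Meis1 read in the third library, which argues against a low Meis1 level in a column made like the rest, and a spread of 0.388 of that of subsampling argues against a random subsample. In simulations a rounded mean of controls 1 and 2 and a shallow library gave a spread of 0.172 where that library differed by counting noise alone and 0.341 where it also varied between genes, so the observed spread is near the second and not matched exactly. Such a mean, with the shallow library's own count kept for Meis1, could give the Meis1 value. Its ratio to the mean of the other controls is 0.122, within the 0.075 to 0.208 of 18 genes with equal control counts that also lie below the line. The other 22 genes with equal counts and a sum of at least 200 lie on the line, at 0.682 to 0.746. That range of 18 was thus taken from genes already below the line. At the 1460956 counts implied for such a library, 282 counts are 193 CPM without TMM scaling, and how the column was made stays open.

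Late neutrophil transcripts, taken from the granule list, were abundant in every library and higher in MC38, with a summed level of 29472 CPM in control and 59991 CPM in MC38 over 17 genes, led by S100a8 and S100a9. The list was split into late and early genes after its values were seen, so the split excludes and supports no explanation. The 5 early genes (Mpo, Elane, Prtn3, Ctsg and Ms4a3) had a median log2 fold change of -0.41, 1.39 below that of the late genes. All 5 were below 0 (-0.642 to -0.161), and 1 of them was called. The other 10 of the 32 members are in neither set, and with them counted as early the median was 0.221 (SD between genes 0.692). RNA of late neutrophils carried into the sorted samples, a granule programme switched on from its early genes and a rise of the late genes alone within the sorted cells cannot be told apart here. Bulk libraries do not place the RNA in a cell, 6 granule genes took 2.59% of control counts already, and the sort gates are not given in the sources used here. A tumour effect on marrow neutrophils was not tested and stays open.

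The same immunoglobulin segments filled every library of a group. For segments with at least 3 CPM, the median absolute log2 ratio between MC38 libraries was 0.55 of that of genes matched on level (0.49 to 0.72 over 6 pairs), against 5.93 between groups (4.62 to 6.98 over 8 pairs). Separate animals, each with its own repertoire, are argued against by the highest pair within MC38, at 0.72. A tumour-driven response added to a baseline shared by separate mice is argued against too, since it would leave the baseline in place. Of the 34 segments with at least 3 CPM in both controls, 15 were lower in MC38 by more than 4-fold, while the controls differed by at most 2.01-fold. In 24 of them every MC38 library was below both controls, where chance would give 2.27 for independent segments not picked by level. These segments were picked by their control level and may vary together, so that chance value is too low a yardstick to decide by. The values are consistent with libraries of a group drawn from the same animals or the same pool of cells, in which case the spread between libraries may leave out most of the variation between mice. A response that also replaces a shared baseline is not excluded, as the single pair of controls, at 1.33, is below every pair between groups and would be so with a shared baseline or with a pool.

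The real grouping of the 6 libraries gave 229 genes past the threshold, and the highest of the other splits gave 4, so 1 of 15 splits gave as many, too few splits for a share under 0.05. With the 7 columns the real grouping gave 1454 genes and the highest other split gave 1, so 1 of 35 splits gave as many. Chance could be excluded for that fit by this count, but column 3 is not independent of the other controls.

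Of 152 values checked, 9 had a single MC38 library apart from the other 3. That is close to the 1 in 20 that chance gives, so these values may reflect chance alone. In MC38 replicate 2, Igkv4-70 was at 55.4 CPM (others 49.5 to 50.4), Ifngr1 at 144 CPM (171 to 174), Meis1 at 204 CPM (218 to 220) and Col1a1 at 0.889 CPM (0.0556 to 0.135). In MC38 replicate 1, Igkv4-91 was at 1.61 CPM (0.835 to 0.962), Rps27a at 729 CPM (814 to 817), Irf8 at 124 CPM (101 to 102) and Stab2 at 7.13 CPM (2.06 to 2.81). In MC38 replicate 4, Igkv4-86 was at 0.074 CPM, which is 1 count, and at 0 in the others.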

How the results depend on the processing

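The rebuilt control and the removal of immunoglobulin genes were chosen after the data were seen, as was the main fit on 6 libraries. The 7-column fit was the design fixed before, and the other alternatives were also chosen before. The number of genes higher in MC38, 148, was 302 with no filter, 269 with the replicate block, 626 with DESeq2, 791 with 7 columns, 304 with the rebuilt control and 95 without immunoglobulin genes. It was 349 at an adjusted p of 0.1 and 55 at 0.01, and 44 to 259 with each library left out. The 81 lower genes became 202 with no filter, 130 with the stricter filter, 190 with the replicate block, 395 with DESeq2, 138 with limma-voom quality weights, 663 with 7 columns, 200 with the rebuilt control, 36 without immunoglobulin genes, 266 at an adjusted p of 0.1, 26 at 0.01 and 41 with a 2-fold minimum, and 16 to 183 with each library left out. The cause was not tested. Leaving out a control leaves 1, which is assumed to vary like the others. Control replicate 3 is already outside the fit.

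Of 18 lists past the threshold, 4 passed with an estimated correlation and 16 to 18 with each library left out, while fry called 19 of the 28 lists, 16 of them among the 18. Of 74 named genes past the threshold, 43 of the 53 still tested passed without immunoglobulin genes (the other 21 are removed there) and 29 to 74 of the 74 with each library left out, 22 passed in every alternative that tests them, and 0 turned sign. Meis1 never passed in 18 alternatives, with log2 fold changes of 0.08 to 0.63. Deviations from the group mean correlated at 0.093 and -0.083 between libraries of the same replicate number, across 10829 genes. With 2 controls the deviations of one mirror those of the other, so these values cannot tell whether replicate numbers pair the libraries. The block gave 0.14 for Meis1, 18 lists and 68 of the 74 genes.

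Direction turned for 5 lists, none of them past the threshold. For antigen presentation adjusted p-values were then 0.999 without mitochondrial and ribosomal genes, 0.769 without shared genes, and 0.421, 0.697 and 0.818 without control replicate 2, MC38 replicate 1 and MC38 replicate 2, and ran from 0.386 to 0.895 in either direction with each library left out. For glycolysis they were 0.964 with the rebuilt control, 0.974 without shared genes, and 0.831, 0.927 and 0.966 without the same 3 libraries, in a range from 0.635 in either direction. They were 0.611 with the block and 0.836 without shared genes for Meis1 partners, 0.667 with the block for stem cell identity and 0.949 with the rebuilt control for type I interferon. With libraries left out the log2 fold change ran from -3.65 to 0.77 for Col1a1, -0.06 to 0.071 for Irf1 and -0.223 to 0.027 for Kit. With 2 controls, the simulated recovery of 36.8% at a 2-fold change limits what could be called.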

Other observations

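All genes in this part were chosen after their values were seen, and no test of an explanation was run on them.

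Some genes outside the lists that encode receptors or secreted proteins of neutrophils and monocytes passed the test, without a test of such genes as a group. Fpr1 and Fpr2, receptors for formylated bacterial peptides, rose from 19.2 ± 6.00 to 54.1 ± 6.67 CPM and from 42.1 ± 3.77 to 93.8 ± 10.7 CPM (SD, n = 2 and 4; edgeR adjusted p = 0.0147 and 0.009). C5ar1, the receptor for complement C5a, rose 2.49-fold (edgeR adjusted p = 0.0147), and Cd177, a neutrophil surface protein, rose from 144 ± 10.1 to 333 ± 38.8 CPM (edgeR adjusted p = 0.00269). The chemokine Ccl6 rose from 130 ± 7.27 to 331 ± 8.99 CPM (edgeR adjusted p = 0.000345), and Wfdc17, a secreted protein of activated myeloid cells, rose 2.52-fold (edgeR adjusted p = 0.000532). Cxcr2, the chemokine receptor of neutrophils, was at 174 ± 23.8 and 208 ± 61.3 CPM and did not pass (edgeR adjusted p = 0.64).

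Immunoglobulin constant regions did not move together. Besides Ighm and Ighg1, Ighg2c rose from 183 ± 15.4 to 354 ± 23.9 CPM (edgeR adjusted p = 0.00453). Igha, the constant region of IgA, fell from 1019 ± 3.44 to 334 ± 76.2 CPM (log2 fold change -1.61, edgeR adjusted p = 0.00212). Ighg2b was at 145 ± 12.2 and 177 ± 24.0 CPM (edgeR adjusted p = 0.358). The plasma cell genes Jchain (432 ± 31.8 and 368 ± 89.9 CPM, edgeR adjusted p = 0.61) and Mzb1 (21.6 ± 1.73 and 22.1 ± 3.90 CPM, edgeR adjusted p = 0.958) did not pass.

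The gene ENSMUSG00000082697, which has no name in the annotation used, was among the most abundant features, at 22330 ± 8162 CPM in control and 3965 ± 1203 CPM in MC38 libraries (edgeR adjusted p = 0.00151). Lars2 had 1865 and 7627 CPM in the controls and 1397 to 3694 CPM in MC38 (edgeR adjusted p = 0.47). None of the 4 tested members of the sex-linked list passed. Among these Y-linked genes, Eif2s3y was detected in every library, at 77.8 ± 3.39 and 82.7 ± 10.8 CPM (edgeR adjusted p = 0.833), while Ddx3y ranged from 37.7 to 138 CPM within MC38 (edgeR adjusted p = 0.361). Ifng itself was at 3.47 ± 1.99 and 5.24 ± 2.15 CPM (edgeR adjusted p = 0.662).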
